A study of Mus musculus with 6 samples.

How the data were processed

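RNA from 6 samples of sorted mouse LSK cells was amplified linearly in 2 rounds and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols. The deposited values are signal intensity values on a linear scale made with MAS5, per the submitters' processing notes, which give no version. The values themselves show a scaling per array, since the mean without the extreme 2% at each end lay between 109.8 and 112 on all arrays, and a floor, since no signal lay below 30. The scaling target and the step that set the floor are not given in the sources used here. Repeated amplification favours the 3′ ends of transcripts, and a floor hides differences among weak genes: 17046 of 45037 probe sets were at 30 on all 6 arrays.

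Groups came from the genotype labels, 3 Ercc1-deficient and 3 Ercc1-proficient samples, each on its own array. The sources used here do not say whether a sample came from 1 mouse or from several of a litter, so p-values measure the spread between these samples. The labels say that arrays of the same number are litter mates, so the numbers pair the samples. The deviations of litter mates from their group means correlated across probe sets with r = 0.77, 0.67 and 0.46 in litters 1, 2 and 3. No 2 arrays held identical values.

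Signals were transformed as log2(signal + 30), the pseudocount being the 10th percentile of all values. A log2 difference on this scale understates the change of weak genes. The 64 control probe sets were left out, and the 22519 probe sets with a mean at or above the median were tested. The fit was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) with group as its only term, and Benjamini-Hochberg adjustment at 0.05. This design, the alternatives with litter as a block, other normalizations, pseudocounts, filters and variance models and with arrays left out, the gene lists and the rule for named genes were fixed before the data were examined. Because litter as a block changed the calls, its values stand beside the results. Where a group was at the floor on all arrays, the fold is a lower bound, from the mean log2 signal of the brighter group against the floor.

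Probe sets were named through the platform annotation of 2016: 34945 had 1 gene symbol, 932 several and 9160 none, and only those with 1 symbol were named. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, which matched 34754 and changed 0; it served only for names and gene neighbours. Some genes of the lists, Ly6a among them, had no probe set of their own and are not used here. Of 30 gene lists fixed in advance, the sex-linked one was described and 29 were tested with camera (limma) at a preset correlation of 0.01, on the brightest probe set of each of 10879 genes. An estimated correlation, the mean over a gene's probe sets and fry, which asks whether a list's genes move on balance 1 way, were alternatives. The adjusted p of a list member is over these genes, or over the list alone where said.

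The named genes were Ercc1, up to 12 genes per direction that passed, filled up to 12 with those of smallest p having a log2 difference of at least 1 and no overlap between groups, the leading members of each list, and all sex-linked genes. The 3′ to 5′ differences of the Actb and Gapdh controls were compared by exact two-sided permutation tests, as were the mean log2 signals of 18S ribosomal RNA and of the spike-ins bioB, bioC, bioD and cre, which are added to the hybridisation mix on such arrays.

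The fits were tested on simulated data with 200 probe sets changed by 2-fold or 4-fold among 22519. The changed ones were drawn from brighter probe sets, well above the filter, so recovery was not measured for weak probe sets. Litter effects and noise followed the model of the blocked fit, which favours that fit where litter effects are present. Without litter effects, the fit without a litter term recovered 73% of 2-fold and 100% of 4-fold changes. With the litter effects of these data it recovered 0% of either, and the blocked fit 73% and 99%. The simulated noise was independent between genes, so the simulation does not test the preset correlation of camera.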

Results

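Gene expression was measured in LSK cells, the lineage-negative, Sca-1-positive, c-Kit-positive fraction of mouse bone marrow that holds blood stem cells and multipotent progenitors. The 3 Ercc1-deficient arrays came from mice carrying 1 knockout and 1 truncated allele of Ercc1, which encodes a subunit of an endonuclease used in nucleotide excision and interstrand crosslink repair. The 3 Ercc1-proficient arrays came from litter mates with at least 1 normal allele; the control of litter 3 also carried 1 truncated allele. Litter 1 was aged 22 weeks and litters 2 and 3 were aged 20 weeks. Each of the 6 arrays gave a signal for 45037 probe sets that were not controls, and between 52.3% and 58.6% of these signals lay at the floor of 30. With 3 arrays per group, their number limits the precision of every comparison. The comparison asked how gene expression in LSK cells differs when Ercc1 function is reduced.

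Ercc1 itself was measured first. Its brightest probe set had a mean signal of 53.1 ± 23.8 (SD, n = 3) in deficient cells and 183 ± 58.3 (SD, n = 3) in proficient cells, and the deficient array was the lower one in all 3 litters. The log2 difference was -1.36 with a standard error of 0.35 (limma, adjusted p = 0.9998). With litter as a block it had an adjusted p of 0.0159 in limma. The exact two-sided permutation test gave p = 0.1, the smallest value that 3 arrays against 3 can give. A second Ercc1 probe set was at the floor in all 3 deficient arrays and averaged 52.7 ± 18.2 (SD, n = 3) in proficient arrays, at least 1.68-fold higher, but did not pass with litter as a block (limma, adjusted p = 0.301). Another 2 Ercc1 probe sets were at the floor on all 6 arrays. Where these probe sets lie relative to the disrupted part of the gene is not given in the sources used here, so they are a limited check of the genotype labels.

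Litter mates resembled each other. In the plot of principal components, the first component held 59.7% of the variance and set both arrays of litter 1 apart from the other litters. Without a litter term, limma called 0 of 22519 probe sets at an adjusted p under 0.05, and 583 had an unadjusted p under 0.05, where 1126 would be expected by chance. With litter as a block, 177 probe sets passed, 66 higher and 111 lower in deficient cells, and 2569 had an unadjusted p under 0.05. The blocked count rested on all 3 litters: it was 0 without litter 1, 0 without litter 2 and 5 without litter 3, and it was 0 when all 45037 probe sets were tested, without the filter on mean signal. In simulated arrays with the litter effects of these data, changes were placed in brighter probe sets only. There the fit without a litter term recovered 0% of 4-fold changes and the blocked fit 99%.

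**Figure D1:**
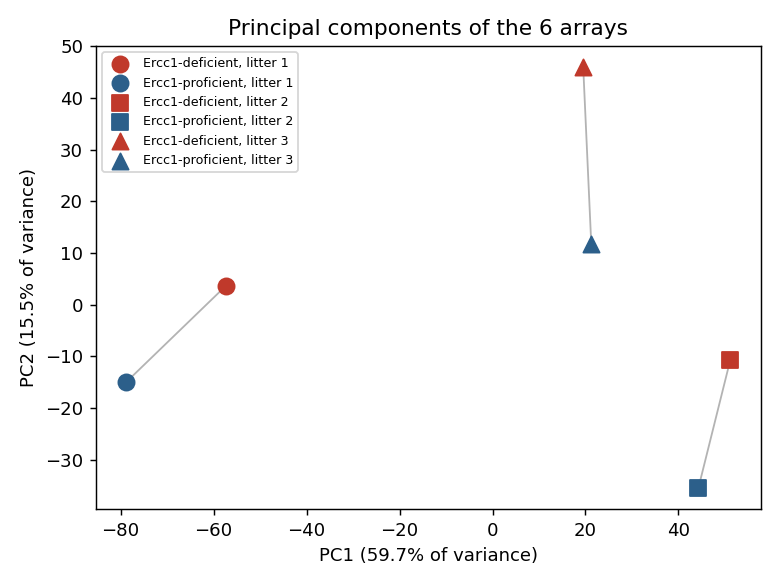
First and second principal components of the 6 arrays, from log2 signals of the tested probe sets; colour gives the group, the symbol gives the litter, and a line joins litter mates. Both arrays of litter 1 lie at negative values of the first component, which held 59.7% of the variance, and those of litters 2 and 3 at positive values.

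Among single genes, those with the smallest p, a log2 difference of at least 1 and no overlap between the groups were named, 12 in each direction. None passed the test without a litter term, and all 24 had an adjusted p under 0.05 with litter as a block, the largest being 0.0160 among the higher and 0.0215 among the lower genes. They were chosen on these same arrays, so passing with the block is not separate support. Higher in deficient cells were Sgms2, a sphingomyelin synthase, at 252 ± 83.1 against 52.8 ± 24.9 (SD, n = 3 each), the chemokine Ccl9 at 1516 ± 205 against 558 ± 141, and Tcl1b3 at 739 ± 218 against 229 ± 34.0. The others were Pilrb1, 9630013D21Rik, Afap1, Fbxo36, Fstl3, Slfn4, Rflnb, Pram1 and Ap3s1. Lower was Dntt, the template-independent DNA polymerase of early lymphoid cells, at 397 ± 84.7 against 2103 ± 822 (log2 difference -2.27, standard error 0.42). Zc3h4 measured 42.2 ± 9.47 against 420 ± 375, and Ldhb, a lactate dehydrogenase subunit, 143 ± 61.4 against 488 ± 165. The imprinted gene Ndn was at the floor in all deficient arrays by the probe set with the smallest p and at 162 ± 27.8 in proficient arrays, at least 5.35-fold higher. Cyp2j9 was likewise at the floor in all deficient arrays and at least 3.05-fold higher in proficient ones. Pgr, Itsn1, Wfdc18, Stxbp4, Zfp827, Eya1 and Ercc1 completed the lower genes.

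Genes of granulocytes were higher in Ercc1-deficient LSK cells. Of 21 measured genes of macrophages and mature granulocytes, 21 were higher, with a median log2 difference of 0.60, and of 24 genes of granulocyte-monocyte priming 23 were higher, with a median of 0.70. Camp, a granule antimicrobial peptide, averaged 3705 ± 5349 in deficient and 367 ± 485 in proficient cells (SD, n = 3 each), with a deficient-over-proficient ratio of 8.06, 6.71 and 10.7 in litters 1, 2 and 3. S100a9, a subunit of calprotectin, averaged 13726 ± 14004 against 3143 ± 3907, and the granule protease Ctsg 6544 ± 3034 against 2818 ± 2188. With litter as a block, 7 members of the mature list rose, among them Camp, Chil3, Ngp, S100a8 and S100a9, and 12 rose when adjusted over the list alone. In the priming list 9 members rose, including Anxa3, Hp, Igsf6 and Cst7, and 15 when adjusted over the list alone; without a litter term the count was 0 in both lists. The mature list had a camera adjusted p of 9.8e-10 and the priming list one of 2.9e-09 with the preset correlation. With an estimated correlation the adjusted p was 0.355 for the mature list and 0.506 for the priming list. The secondary granule genes Ltf and Lcn2 had signals of 2477 and 3055 in deficient cells of litter 3, but of 39.5 and 30 in those of litter 1, and the log2 difference of Ltf was -0.15 without deficient replicate 3. That fit kept proficient replicate 3. Within litters the deficient-over-proficient ratio of Ltf was 1.32, 1.63 and 20.2, and its log2 difference was 0.30 under the block without litter 3. The spike-in controls bioB, bioC, bioD and cre were also higher in the deficient array of all 3 litters, as was 18S ribosomal RNA.

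**Figure D2:**
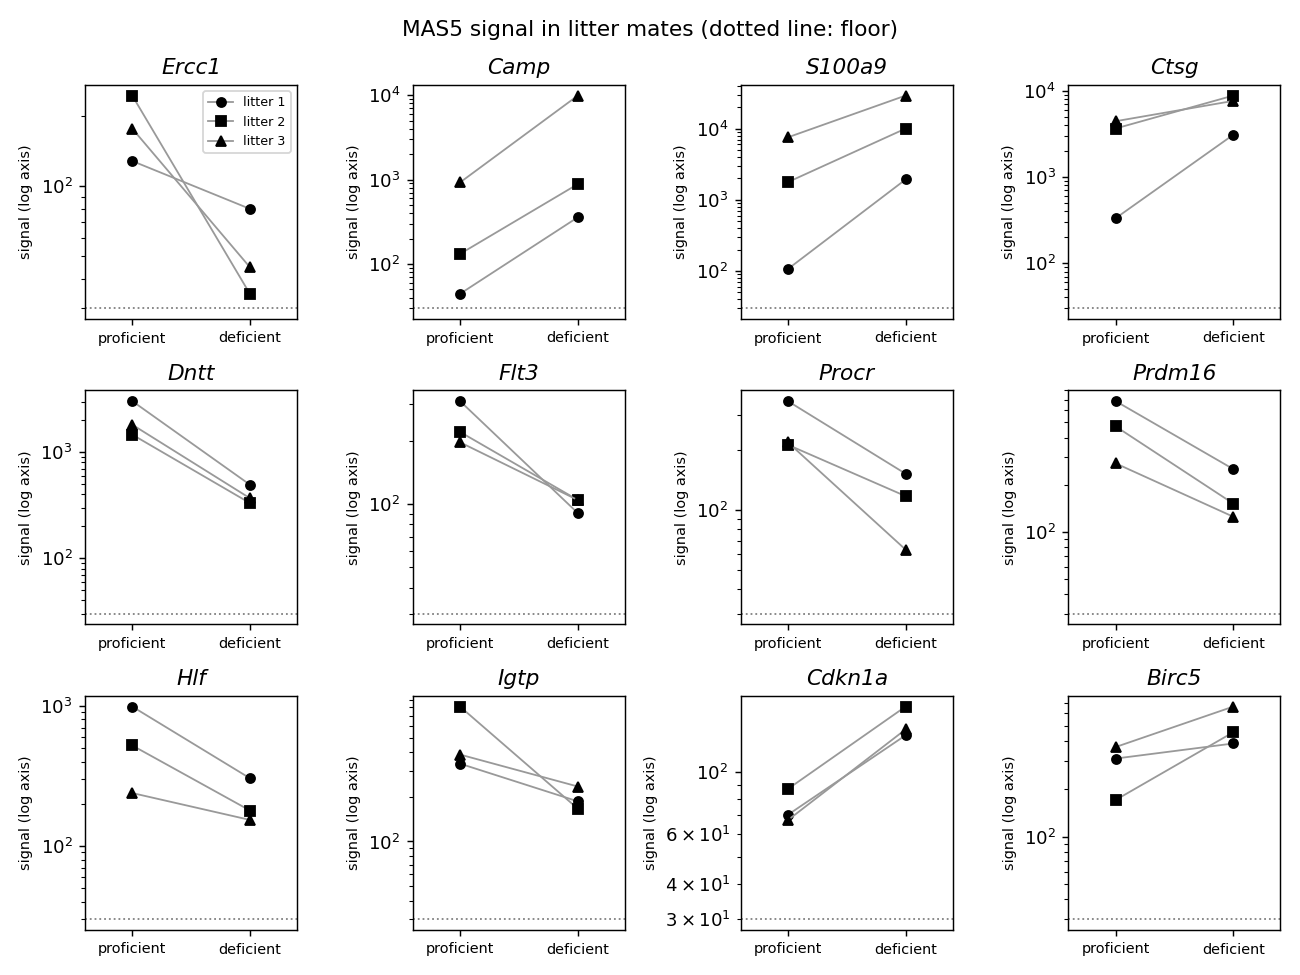
Signal of 12 genes on a log axis in proficient and deficient litter mates, with a line for each litter and the floor of 30 dotted. Camp, S100a9 and Ctsg were higher, and Dntt, Flt3, Procr, Prdm16 and Hlf lower, in the deficient array of all 3 litters, while litters differed widely in level.

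Genes of long-term stem cells were lower in deficient cells. Of 31 measured members 25 were lower, with a median log2 difference of -0.53. Prdm16, a transcriptional regulator of stem cell maintenance, averaged 176 ± 66.8 in deficient and 477 ± 205 in proficient cells (SD, n = 3 each), and Procr, the endothelial protein C receptor used to sort stem cells, 111 ± 44.9 against 262 ± 79.3. Trpc6 was at the floor in all deficient arrays and at least 2.76-fold higher in proficient ones. With litter as a block 6 members fell, namely Ndn, Prdm16, Hlf, Trpc6, Procr and Hoxa9, and 13 fell when adjusted over the list alone. Without a litter term, Trpc6 and Ndn passed when adjusted over the list alone, at 0.0117 and 0.0122. The list had a camera adjusted p of 2.1e-09, and an adjusted p of 0.355 with an estimated correlation. The same spike-in controls and 18S ribosomal RNA were higher where these genes were lower.

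Genes of multipotent progenitors and lymphoid priming were also lower, 17 of 22, with a median log2 difference of -0.45. Dntt and the cytokine receptor gene Flt3 fell with litter as a block; Flt3 averaged 99.9 ± 8.09 in deficient and 243 ± 59.5 in proficient cells (SD, n = 3 each). Adjusted over the list alone with litter as a block, 6 members fell, Cd27 and Ccr9 among them, and 1 rose, Cd48, at 487 ± 84.1 against 282 ± 88.4; without a litter term Dntt alone passed in this way (0.0052). The camera adjusted p was 0.00091, and the adjusted p 0.355 with an estimated correlation. The call rested on litter 1: the adjusted p was 0.0589 without deficient replicate 1, 0.0933 without proficient replicate 1 and 0.434 without that litter, and the litter medians were -0.70, -0.08 and -0.21 in litters 1, 2 and 3.

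Genes of G2/M and mitosis were slightly higher, 33 of 37, with a median log2 difference of 0.28. The litter medians were 0.38, 0.06 and 0.32 in litters 1, 2 and 3. No member passed by itself, with or without litter as a block. Birc5, a mitotic and survival factor, averaged 502 ± 143 in deficient and 283 ± 102 in proficient cells (SD, n = 3 each), and the values of Mad2l1, Ect2 and Ttk were higher in deficient cells of all 3 litters. The camera adjusted p was 6.6e-05, and the adjusted p 0.355 with an estimated correlation. Genes of G1/S and DNA replication had a median of 0.11 and a camera adjusted p of 0.0706, or 0.0232 with litter as a block, 0.0422 with no variance trend, 0.0327 without deficient replicate 1, 0.0391 without proficient replicate 2 and 0.0092 without proficient replicate 3. The adjusted p was 0.746 with litter as a block and an estimated correlation. It was 0.117 under the block with quantile normalization, and 0.469 without litter 1 and without a litter term. The litter medians of this list were 0.36, -0.004 and 0.07, so its shift was largest in litter 1.

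Among genes tied to DNA damage, 19 of 28 p53 target genes were higher, with a median log2 difference of only 0.09. Cdkn1a, an inhibitor of cyclin-dependent kinases, averaged 149 ± 18.9 in deficient and 74.8 ± 10.5 in proficient cells (SD, n = 3 each) and did not pass by itself, with an adjusted p of 0.0902 in limma with litter as a block. The camera adjusted p of the list was 0.0316, and it was not called with litter as a block (0.0785) or with an estimated correlation (adjusted p = 0.355), nor with a stricter filter that kept only the brighter probe sets (0.356), no variance trend (0.0563) or a filter, chosen after seeing the data, for probe sets above the floor on all arrays of 1 group (0.0516), nor without deficient replicate 1 (0.087), deficient replicate 2 (0.168) or proficient replicate 2 (0.198). Nucleotide excision and crosslink repair genes had a median of 0.06 and an adjusted p of 0.852, and Ercc1 alone among the 27 fell with litter as a block. Homologous recombination and damage signalling genes had a median of -0.04 and an adjusted p of 0.879. Senescence and secretory genes were not called (0.401), and 8 of 14 were higher. Adjusted over the list alone with litter as a block, Cdkn1a, Igfbp7 and Mmp9 rose and Ccl3 fell. Ccl3, a chemokine gene, was at the floor in all deficient arrays, at least 2.80-fold higher in proficient ones, and passed adjusted over the list alone without a litter term (0.0190).

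Interferon-induced genes were lower in deficient cells, 24 of 31, with a median log2 difference of -0.20. Xaf1, a proapoptotic interferon-induced gene, averaged 98.5 ± 69.4 in deficient and 260 ± 105 in proficient cells (SD, n = 3 each), and with litter as a block Igtp, Xaf1, Rtp4 and Gbp2 fell, 7 members when adjusted over the list alone. The camera adjusted p was 0.0015, and the adjusted p 0.579 with an estimated correlation, 0.131 without proficient replicate 2 and 0.0544 with litter as a block and litter 2 left out. In antigen presentation 14 of 17 genes were lower, with a median of -0.36; Tap1, Tap2 and H2-K1 fell only when adjusted over the list alone with litter as a block. That list had an adjusted p of 0.0316, and of 0.772 with an estimated correlation; it was 0.709 without deficient replicate 1, 0.262 without proficient replicate 2, 0.435 without proficient replicate 3, and 0.0658 with the Actb 3′ to 5′ difference as a covariate, which was chosen after seeing the data. NF-kB and inflammatory genes were lower in 15 of 18 cases, with a median of -0.21, and Ccl3 and Ier3 fell with litter as a block, 3 members when adjusted over the list alone. Their adjusted p was 0.0087, and 0.355 as the adjusted p with an estimated correlation, 0.151 without a filter, 0.066 without deficient replicate 1, 0.0745 without proficient replicate 1 and 0.164 without litter 1. Immediate early genes had a median of -0.25 and an adjusted p of 0.0616, or 0.0052 without proficient replicate 2 and 0.0398 with litter as a block, where Dusp2 and Ier3 fell; over the list alone 6 fell and 1 rose. The list was also called with quantile normalization (0.0393), median centring (0.0294), no filter (0.0186), the stricter filter (0.0043), the filter on probe sets above the floor (0.0273) and no variance trend (0.0189), but its adjusted p was 0.746 with litter as a block and an estimated correlation. Without litter 1 and without a litter term it was 0.622. The litter medians were -0.46, 0.08 and -0.40, so litter 2 had the opposite sign.

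Genes of the NRF2 and antioxidant defence list were higher in 18 of 25 cases, with a median log2 difference of 0.27. Gsr, glutathione reductase, averaged 1620 ± 837 in deficient and 706 ± 275 in proficient cells (SD, n = 3 each), and Gsr and Pgd rose with litter as a block, 4 members when adjusted over the list alone. The camera adjusted p was 0.0071, and the adjusted p 0.737 with an estimated correlation; the litter medians were 0.61, 0.08 and 0.09. Without deficient replicate 2 the adjusted p was 0.16, without proficient replicate 1 0.982 and without litter 1 0.354. Oxidative phosphorylation genes were higher in 39 of 46 cases, with a median of 0.29, but no member passed by itself and the median was -0.14 in litter 3. Their adjusted p was 0.0090, and 0.955 as the adjusted p with an estimated correlation, 0.117 with quantile normalization, 0.0829 with median centring, 0.855 without deficient replicate 2, 0.16 without deficient replicate 3 and 0.177 without litter 1. The direction of that test turned without proficient replicate 1 (0.102).

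Other cell types the gate could hold were examined through their markers. Mature B and T cell genes were higher in 9 of 12 cases, with a median log2 difference of 0.16 and an adjusted p of 0.0175, or an adjusted p of 0.584 with an estimated correlation. With the preset correlation that p was 0.0673 with quantile normalization, 0.14 without a filter, 0.0774 without litter 1, 0.417 without deficient replicate 2, 0.168 without proficient replicate 1 and 0.12 without proficient replicate 2. The member that rose with litter as a block was Nkg7, a cytotoxic granule gene also used by natural killer cells, at 999 ± 350 against 542 ± 254 (SD, n = 3 each), while Cd3d, Cd8a and Cd3e had mean signals of 43.9, 52.8 and 50.2 in deficient cells, near the floor, and Cd3e turned sign without litter 1. Megakaryocyte and platelet genes had a median of -0.08 and an adjusted p of 0.947, and Selp rose with litter as a block, 2 members rising and 1 falling over the list alone. Erythroid genes had a median of -0.14 and an adjusted p of 0.535, which was 0.00074 without proficient replicate 1 and 0.0164 without litter 1. Stroma, endothelium and fat genes had a median of -0.02 and an adjusted p of 0.986. Genes described as higher in aged stem cells had a median of -0.07 and an adjusted p of 0.933; Selp and Gda rose with litter as a block, and over the list alone 4 rose and 4 fell. The remaining lists were not called with or without litter as a block: apoptosis regulators (adjusted p = 0.395), quiescence and cell cycle inhibitors (0.852), heat shock and unfolded protein response (0.852), glycolysis (0.401), ribosomal proteins (0.0706), sterol and fatty acid synthesis (0.78), the IGF1 and growth hormone axis (0.947) and the neighbours of Ercc1 (0.852). Of these, the quiescence list was called without proficient replicate 2 (0.0317), and the ribosomal list with no variance trend (0.0422) and without deficient replicate 1 (0.00022), proficient replicate 2 (0.0021) or proficient replicate 3 (0.0032).

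**Figure D3:**
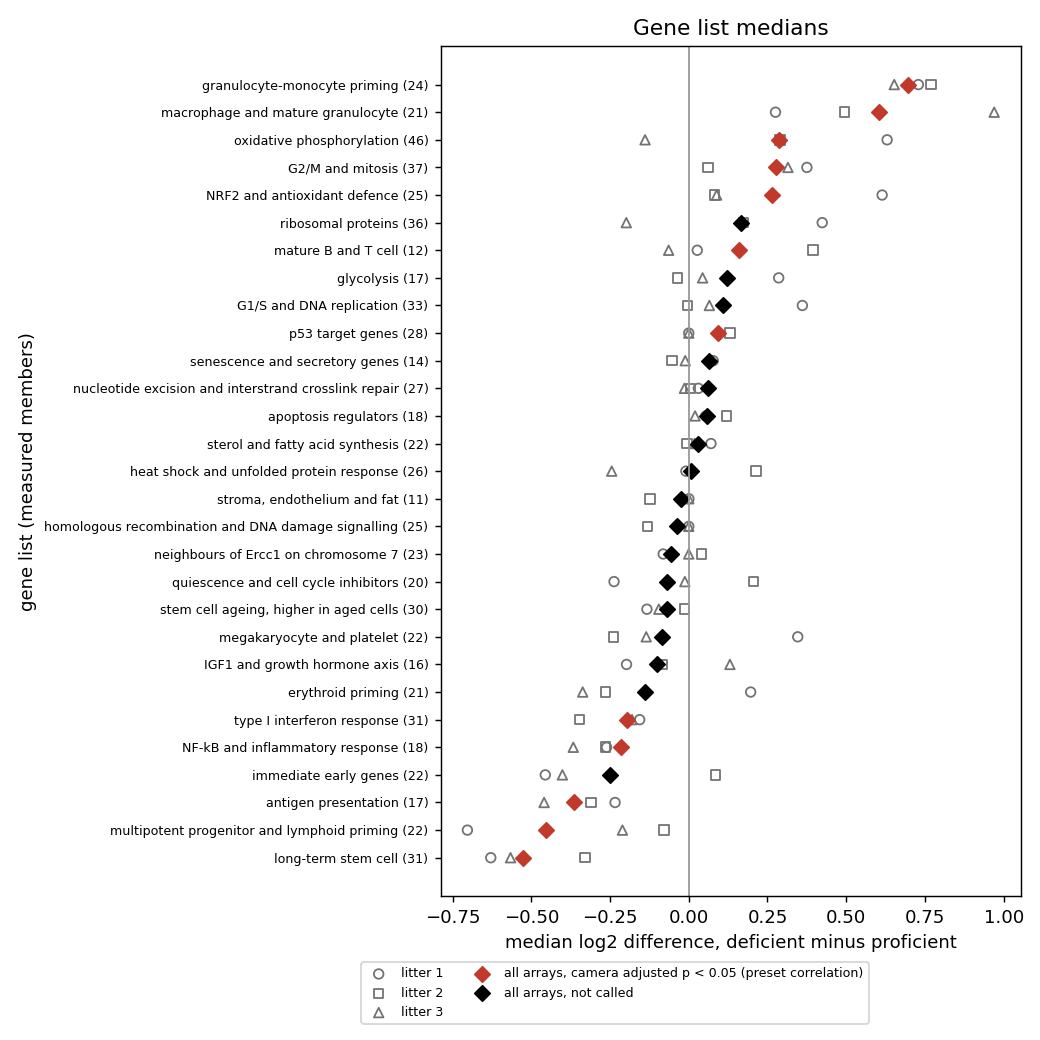
Median log2 difference, deficient minus proficient, of each gene list over all arrays (filled) and in each litter (open symbols); red marks lists with a camera adjusted p under 0.05 at the preset correlation. The 2 granulocyte lists lie above 0 and the long-term stem cell list below 0 in all 3 litters.

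Across the 29 lists tested, camera called 12 with the preset correlation, 7 of them higher, and 0 with an estimated correlation. With litter as a block it called 13, and again 0 with an estimated correlation. The self-contained test fry, for a shift in 1 direction, called 0 lists with or without litter as a block. Its test for changes in either direction called 3 lists without a litter term, namely senescence and secretory genes (adjusted p = 0.00067), NF-kB and inflammatory genes (0.0114) and long-term stem cells (0.0264), and 9 with litter as a block. In every setting run other than fry and the estimated correlation, 4 of the 12 lists were called: both granulocyte lists, long-term stem cells, and G2/M and mitosis. The other 8 lost their call in at least 1. Of the 13 lists called under the block, 6 kept their call when litter 1 was left out. Among the calls that ended were those of multipotent progenitor (adjusted p = 0.724), mature B and T cell (0.158), NF-kB (0.168), NRF2 (0.362) and oxidative phosphorylation genes (0.158). Under the block, leaving out litter 2 also ended the call of mature B and T cell genes (0.621).

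Control transcripts differed in 1 direction within litters, which holds beside every gene list whose litter medians share 1 sign. Of 18 probe sets for the spike-ins bioB, bioC, bioD and cre, 17 were higher in the deficient array of all 3 litters. The mean log2 signal of cre was 14.69 ± 0.41 in deficient and 14.19 ± 0.18 in proficient arrays (SD, n = 3 each), with differences of 1.10, 0.20 and 0.17 in litters 1, 2 and 3, and those of bioB were 1.24, 0.06 and 0.16. The groups did not overlap for bioC and bioD (exact two-sided permutation p = 0.1 for each, the smallest possible). The difference for 18S ribosomal RNA was 0.05, 0.88 and 0.64. A paired exact test over litters gave 0.25 for each of these 5 controls, the smallest p that 3 pairs allow. The log2 difference between the 3′ and 5′ probe sets of Actb averaged 4.18 ± 0.84 in deficient and 4.06 ± 0.37 in proficient arrays (SD, n = 3 each; exact two-sided permutation p = 0.9, where 0.1 is the smallest possible). The deficient array exceeded its litter mate by 0.92 in litter 1 and lay below it in litters 2 and 3, by -0.16 and -0.41. Sex-linked genes differed between litters: the brightest Xist probe set read 114 and 166 in litter 1, and between 5087 and 14652 in the other 4 arrays. The Y-linked gene Eif2s3y read 452 and 828 in litter 1, and 76.8 and 169 in deficient arrays 2 and 3 against 30 in both of their litter mates. Another Y-linked gene, Kdm5d, read 239 and 201 in litter 1 by its brightest probe set, 42.1 in deficient array 2 against 48.9 in its litter mate, and 65.8 against 30 in litter 3. The sex of the mice is not given in the sources used here, and these genes do not settle whether these arrays hold RNA of 1 animal only, which limits every difference between the groups.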

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

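The litter term decided the count of probe sets. Under the replicate block, which was planned, 177 probe sets passed where 0 did without it, and 2569 in place of 583 had an unadjusted p under 0.05 (limma). The other settings without that block gave 0 passing probe sets. The unadjusted count was 221 with the stricter filter, which tested fewer probe sets, and 1015 without the 22-week-old litter. Leaving out single arrays gave between 443 and 782 of these. The 25th percentile of the values is also 30, so that pseudocount was not run separately.

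Combinations with the replicate block were chosen after seeing the data. They gave 124 passing and 2315 unadjusted probe sets with quantile normalization, 204 and 2603 without a pseudocount, 212 and 1585 with the stricter filter, and 255 and 2522 over probe sets above the floor on all arrays of 1 group. Without a filter the block gave 0 and 1825. Without litter 1 it gave 0 and 1291, without litter 2 it gave 0 and 1380, and without litter 3 it gave 5 and 1717. Each of these leaves 2 pairs. The number of probe sets alone does not account for the 0 without a filter. With the filter, Camp had an unadjusted p of 1.2e-10 under the block (limma), small enough to pass among 45037 probe sets too. Without a filter, the variance trend was fitted over probe sets that included 17046 at the floor on all arrays. Whether these changed the p-values was not tested. The other counts differ in sample or probe set numbers, and causes beyond these were not tested.

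The Ercc1 log2 difference of -1.36 kept its sign in every alternative run. It passed the threshold under the replicate block (-1.36, adjusted p = 0.0159), and under the block with quantile normalization (-1.30), without a pseudocount (-1.83), with the stricter filter (-1.36) and with the filter on the floor (-1.36). It did not pass under the block without a filter or without any 1 litter. Adjusted p over all its alternatives ran from 0.0039 to 1.

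Camera called 12 lists with the preset correlation and 0 with an estimated one, fry 0 for a shift in 1 direction, and the replicate block 13, of which 11 were among the 12. With the block and an estimated correlation, or fry in 1 direction, the number was 0, and it was 7 under the block without litter 1. Leaving out single arrays gave 8 to 13 lists. The block lost the p53 targets and gained G1/S and immediate early genes; it changed no other list call. The oxidative phosphorylation list turned its direction without proficient replicate 1, where its adjusted p was 0.102; over the arrays left out, that p ran from 2.68e-06 to 0.855. The named genes that turned sign did not pass in the fits concerned. The log2 differences of Myb and Lmo2 were 0.049 and 0.033 with median centring, and that of Lmo2 was 0.073 under the block without litter 3. Cd3e read -0.015 without the 22-week-old litter, with or without the block. Over single arrays left out, Cd3e ran from -0.0100 to 0.49, Ltf from -0.15 (without deficient replicate 3) to 2.44, Myb from -0.15 to 0.078 and Lmo2 from -0.18 to 0.053. The signal floor limits weak genes, as 55.1% of values lay at it.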

Other observations

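The tests of 3′ excess, control transcripts, neutrophils, primary granule genes, dilution, neighbouring genes and imprinted genes below were chosen after the results they bear on were seen; the counts over other splits were planned before.

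Genes with roles across stem and progenitor cells did not move together. Lmo2, Gata2, Lyl1 and Kit among them belong to the long-term stem cell list fixed in advance. Myb averaged 5786 ± 914 in deficient and 5953 ± 942 in proficient cells and Lmo2 2352 ± 401 against 2440 ± 313 (SD, n = 3 each). Gata2 averaged 645 ± 116 against 444 ± 50.9, and Kit, whose product was used in the sort, 104 ± 17.7 against 168 ± 56.0. None of the 8 passed limma with litter as a block, where Kit had an adjusted p of 0.317. The heat shock gene Hspa1b fell with litter as a block, from 429 ± 564 in proficient to 53.5 ± 20.6 in deficient cells, in a list that was not called.

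With 6 arrays, other splits cannot give a share under 0.05. All 10 of the 10 splits into 3 and 3 gave at least the 0 probe sets of the real one, and the highest other gave 51. That split put the arrays of litter 1 in one group and those of litter 2 in the other. Splits that set litter 1 against another litter gave 1471 to 3953 probe sets with an unadjusted p under 0.05 (limma). Those that set litter 2 against litter 3 gave 780 and 504, so the structure is mainly that of litter 1 against the others. Litter 1 also differed in age and in its sex-linked genes, and these cannot be told apart. With litter as a block, 1 of the 4 splits that part all litter pairs, the real one, gave 177 probe sets, and the highest other gave 0. For gene lists called at the preset correlation, 1 of 10 splits, the real one with 12, gave as many, but the others gave 5 to 10. Calls of single lists at that correlation are therefore frequent under groupings that do not follow genotype.

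For the higher granulocyte-monocyte priming genes, the tables argue against 3′ excess as the whole cause: that of Actb and Gapdh was higher in the deficient array of litter 1 and lower in those of litters 2 and 3, while the median of this list was 0.73, 0.77 and 0.65, the last being the lowest where both differences were below 0; for the mature granulocyte list it stays open, since the medians were 0.28, 0.49 and 0.97, with an SD of 0.35, and the lowest where both differences were below 0 was 0.49. A difference in RNA input or array processing stays open. Both 18S ribosomal RNA and the spike-ins were higher in the deficient array in all 3 litters and so follow the genotype. In size they did not track the priming medians, with differences of 1.10, 0.20 and 0.17 for cre and 0.05, 0.88 and 0.64 for 18S. How far such differences could shift the lists was not tested. The Actb covariate moved 0 probe sets by over 0.5 and does not bear on this. It ended 1 list call, antigen presentation (camera adjusted p = 0.0658). The gains of the primary granule genes Mpo, Elane, Prtn3 and Ctsg relative to Camp were at least 4.33 times higher in litters 1 and 2 than in litter 3 (2.11 on the log2 scale, with an SD of 0.98 between the ratios). All these ratios share the array pair of litter 3, and the SD between them does not measure the error of that pair. For Elane the result also depends on the reference gene. From litter 1 to litter 3 the gain of Elane went from 36.1 to 238 and that of S100a8 from 2824 to 16817. Relative to S100a8, Elane thus gained no more in litter 1 than in litter 3, though it gained more in litter 2. Its gain in litter 1 was 2.20-fold and so came from signals near the floor. Mpo, Prtn3 and Ctsg gained more relative to S100a8 in litters 1 and 2 than in litter 3. Since every ratio rests on the pair of litter 3, 1 source of fixed profile behind all granule gene gains, such as mature neutrophils, stays open. Mature neutrophils may contribute to part of the pattern, most plainly in litter 3, where Ltf and Lcn2 gained 0.26 and 0.33 of the gain of Camp. In litters 1 and 2 this share was at most 0.082, but from signals near the floor. For the mature granule genes, neutrophils and a change in progenitors, which stays a hypothesis, therefore cannot be told apart. Less mature granulocytic cells were not tested. The lineage depletion and the sort were meant to remove mature cells, but whether some remained was not measured. S100a9, at 29204, was the highest signal of deficient array 3.

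The lower stem cell genes were weighed against dilution by cells that lack stem and progenitor RNA. The 8 genes used across these cells had a median log2 difference of -0.049, against -0.56 for the 27 other stem cell genes, a gap larger than the SD of 0.32 between the 8. Lmo2, Gata2, Lyl1 and Kit were moved from the stem cell list to the 8, which widens the gap slightly, as the whole list had a median of -0.53. Myb, Runx1, Etv6 and Cd93, outside that list, had differences of -0.04, 0.12, -0.35 and 0.13. Over litters the mean gap was 0.52 with a standard error of 0.14. Lmo2, Gata2, Lyl1 and Kit differed by -0.06, 0.50, -0.13 and -0.53, so Kit fell as much as the whole stem cell list. Dilution by cells that lack the RNA of both sets would lower both alike, so it is unlikely to be the whole cause. Cells that hold RNA of the 8 genes but not of the others would spare the 8. Whether such cells were present was not tested. A smaller share of long-term stem cells within the sorted fraction, or lower expression per cell, may each give this pattern and were not tested, and a difference in RNA input or array processing stays open here too.

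Zc3h4 and Apoe, both on chromosome 7 with Ercc1, were among the lower genes, and variants carried along with the targeted alleles are a candidate explanation. Of 58 measured genes among the 100 nearest on each side, 2 (3.4%) were called with litter as a block, against 122 of 10393 other genes (1.2%; one-sided Fisher's exact p = 0.151). With 2 calls, passenger variants and effects of Ercc1 loss cannot be told apart.

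Ndn is imprinted, and a joint shift of imprinted genes was tried as a hypothesis. The 9 measured imprinted genes whose values had not been read before were lower in 9 of 9 cases, with a median log2 difference of -0.26 and none passing by itself. Phlda2, Meg3, Sgce, Mirg and Mest among them had arrays at the floor, and Phlda2, Mirg and Mest differed by only -0.07, -0.04 and -0.02. Over all 13 measured imprinted genes but Ndn, 12 were lower and 1, Igf2, was higher. Camera with litter as a block gave p = 0.0215 with the preset correlation and p = 0.139 with an estimated one, so a joint shift may or may not exist in these data.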
